A study of Homo sapiens with 12 samples.

How the data were processed

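RNA-seq of 12 libraries was analysed, 3 for each of 4 groups of TMD436 cells, a tumour-derived form of MDA-MB-436: pLKO, which the submitters use as the shRNA control, and 3 shRNAs against TONSL. Groups and replicate numbers were taken from the sample labels. The sample titles call the knockdown groups shTONSL Clone1, Clone2 and Clone3, and each was taken here as an shRNA. The titles do not say whether a clone is an shRNA construct or a clone of cells. Per the labels' protocols, cells were grown in MEM with serum, and libraries were made from 1 µg of total RNA. The tools named per the submitters' processing notes were STAR 2.5.2b, featureCounts, Subread 1.5.1 and edgeR, with the build hg38; their roles and options, and the strand used in counting, are not given in the sources used here.

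The authors deposited a single table of 13915 genes. Per the file headers it holds raw read counts per gene for each library, which were used as deposited for all tests. Each gene in it lay above 0.5 CPM in at least 3 libraries (the lowest such value was 0.502), so genes below that level were not analysed here. The table also holds log2 FPKM values per the file headers. These matched log2 values recomputed from the deposited counts with TMM scaling and the deposited gene length (total exon length in bases) within 0.004 for genes with at least 1000 counts, and were otherwise not used. The authors' deposited table further gives a fold change and its log2 value, and a p-value and FDR, for each shRNA against pLKO. At an FDR under 0.05 the authors' deposited table lists 5967, 6692 and 6768 genes, and TONSL at -2.29, -2.09 and -3.90. The exon coordinates of 629 genes, LPAR1 among them, were incomplete in the table and no start or end is given for them, while all genes were placed in 10 Mb windows by the start of their first listed exon.

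Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The filter filterByExpr (minimum count 10) removed 0 genes. Libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, which gives 8 residual degrees of freedom. Contrasts were each shRNA against pLKO, the mean of the 3 shRNAs against pLKO, and each pair of shRNAs. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Standard errors were obtained from the log2 fold change and the square root of its F statistic. CPM are TMM-normalised, as mean ± SD of 3 libraries. Lists were tested with camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over 32 lists, and beside it with an estimated correlation and with fry. Fry asks whether a list's genes move one way on balance, without comparing them with other genes.

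The comparisons, the 34 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except those said to be chosen later. Mitochondrially encoded genes (0 members in the table) and adipocyte markers (3 members) had fewer than the 5 members needed and were not tested. TONSL was always named. For all 3 shRNAs the rule named the 12 rising and 12 falling genes with the largest smallest change, among genes with a symbol, an adjusted p under 0.05 and the same sign with each shRNA, an average log2 CPM of at least 3 and all 9 knockdown libraries on the same side of the pLKO libraries. For each shRNA it named the 6 rising and 6 falling genes of largest change, and for each pair of shRNAs 4 and 4, among genes with an adjusted p under 0.05, a log2 CPM of at least 3 and no overlap between the groups' libraries. Of each list described, up to 4 members with the smallest p were named, and any member of the TONSL partners list. Not every gene that these rules gave is described in the text or drawn.

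Depth ranged from 48.2 to 76.7 M counts per library. The gene test was tested on simulated data for shTONSL-1 against pLKO, with 13915 genes of which 50 were changed at each size. It recovered 72% of genes changed by 0.5 on the log2 scale, 100% at 1 and at 2, and 82% at -0.5, and 11 of its 188 calls were unchanged genes. Transcript GC content was taken from the longest annotated transcript of each gene and matched 13509 of 13915 genes (97.08%). For the GC correction, each library's loess trend of log2 CPM deviation on GC content was removed as an offset. Shared controls were assessed with 20 simulations of unchanged groups, in which the counts of all 12 libraries, the controls included, were drawn from the pLKO means.

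Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, library size alone, a stricter filter on low counts and no filter, only the compared groups in the fit, the replicate number as a block, a 2-fold or a 0.01 threshold, the other list tests, genes with a log2 CPM of at least 3 for the correlations, and leaving out each library. The GC correction and leaving out the genes of shifted 10 Mb windows were added after the data were seen, and shTONSL-3 replicate 2 was singled out then. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. No DNA or protein measurement was used here.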

Results

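RNA was sequenced from TMD436 cells, a tumour-derived form of the breast cancer cell line MDA-MB-436. The cells carried either the pLKO vector, which served as the shRNA control, or 1 of 3 shRNAs against TONSL. The sample titles call the knockdown groups clones, each taken here as an shRNA. Whether differences between these groups come from the shRNAs or from clones of cells cannot be told apart. TONSL is a protein that binds newly made histones at replication forks and acts with MMS22L in homologous recombination. Each of the 4 groups (pLKO, shTONSL-1, shTONSL-2 and shTONSL-3) had 3 libraries, 12 in all. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The counts assigned to genes came to 57.7, 51.2 and 58.8 M in the pLKO libraries. They came to 52.8, 76.7 and 50.1 M with shTONSL-1, 50.4, 48.2 and 69.7 M with shTONSL-2, and 52.2, 61.3 and 60.8 M with shTONSL-3. No pair of replicates differed by as little as sampling noise.

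In shTONSL-3 replicate 2, transcripts rich in G and C were lower, and transcripts poor in them higher, than in its groupmates. Its median log2 difference from the other shTONSL-3 libraries ran from 0.31 in the 20% of genes with the lowest GC content to -0.57 in the 20% with the highest. The difference correlated with GC content across genes (Spearman's rho = -0.782; genes are not independent replicates). Pearson's r of log2 CPM (counts scaled to library size) within groups was 0.989 and 0.986 for the pairs with this library, against 0.997 to 0.998 for the other pairs. The median change of shTONSL-3 against pLKO followed the same order, from 0.18 to -0.32. The common dispersion was 0.0073 with this library and 0.00171 without it.

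**Figure D1:**
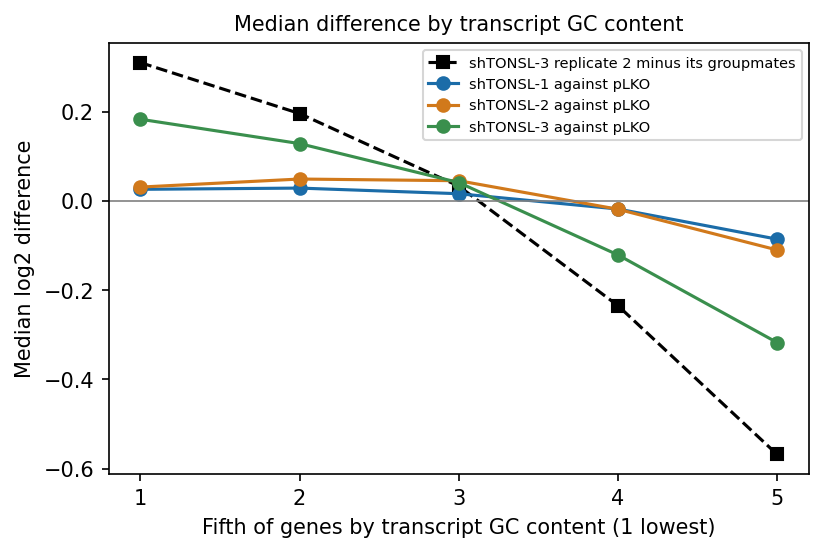
Median log2 difference (y axis) of genes in 5 groups of equal size by transcript GC content (x axis, 1 lowest), for shTONSL-3 replicate 2 minus the other shTONSL-3 libraries (black squares) and for each shRNA group against pLKO (circles). The black line falls from 0.31 to -0.57 and shTONSL-3 against pLKO from 0.18 to -0.32, while shTONSL-1 and shTONSL-2 end at -0.09 and -0.11.

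The first comparison asked whether each shRNA lowered its target. TONSL mRNA (chromosome 8, 144428780 to 144444429, hg38) was lower than in pLKO in all 9 knockdown libraries. It stood at 112 ± 4.28 CPM in pLKO (SD, n = 3), from 6058 to 6520 counts. It was 23.02 ± 0.295 CPM with shTONSL-1 (n = 3), 20.5% of the pLKO mean, and 26.3 ± 0.333 CPM with shTONSL-2 (n = 3), 23.5%. With shTONSL-3 it was 7.53 ± 1.93 CPM (n = 3), 6.70% of the pLKO mean, from 322 to 482 counts. The log2 fold changes against pLKO were -2.29 (SE 0.13, edgeR adjusted p = 2.88e-08), -2.09 (SE 0.12, edgeR adjusted p = 4.29e-08) and -3.90 (SE 0.14, edgeR adjusted p = 1.49e-09). TONSL was lower with shTONSL-3 than with shTONSL-1 by a log2 difference of -1.62 (SE 0.13, edgeR adjusted p = 2.94e-06) and than with shTONSL-2 by -1.81 (SE 0.13, edgeR adjusted p = 1.29e-06). shTONSL-2 and shTONSL-1 differed by 0.19 (SE 0.12), which did not pass (edgeR adjusted p = 0.294). That difference passed without shTONSL-3 replicate 2 (edgeR adjusted p = 0.00715), after GC correction (edgeR adjusted p = 0.00347) and with only these groups in the fit (edgeR adjusted p = 0.00214), the lowest of its alternatives.

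**Figure D2:**
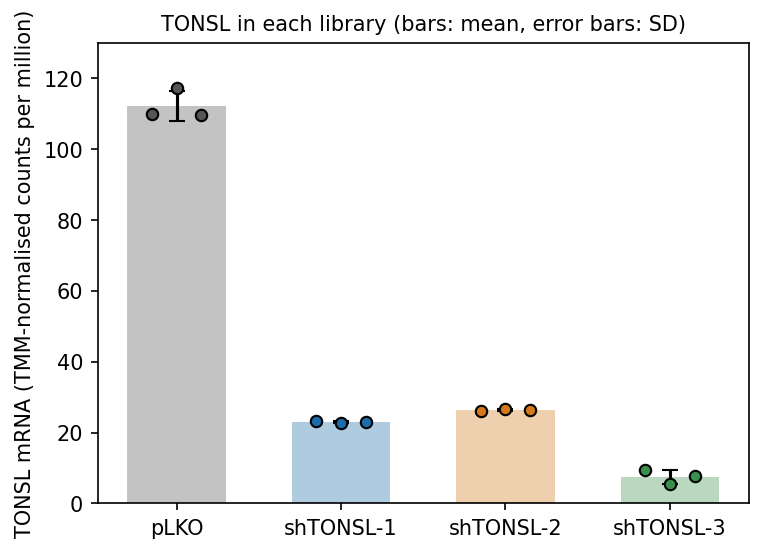
TONSL mRNA in TMM-normalised CPM (y axis) in each group (x axis); points are the 12 libraries, bars the mean of 3 and error bars the SD. The means were 112 in pLKO, 23.02 with shTONSL-1, 26.3 with shTONSL-2 and 7.53 with shTONSL-3.

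The next comparison asked which genes changed with the knockdown whichever shRNA was used. Among the largest shared rises was that of TPM2, which encodes the actin-binding protein beta-tropomyosin (chromosome 9, 35681993 to 35690056). It went from 10.8 ± 0.328 CPM in pLKO to 102.1 ± 3.78 with shTONSL-1, 102.4 ± 1.15 with shTONSL-2 and 57.8 ± 4.68 with shTONSL-3 (SD, n = 3 each). PRICKLE1 (planar cell polarity), ATP2B1 (plasma membrane calcium pump) and LRRN1 also rose. INSIG1, which holds the sterol sensor SCAP in the endoplasmic reticulum, rose from 37.9 ± 2.80 CPM to 167 ± 6.05, 124 ± 4.94 and 108 ± 5.06 (n = 3 each). Among the genes that fell were the interferon-induced RSAD2, OASL, DDX60, IFI44 and ISG15, the basement membrane gene NID2, and the chemokines CXCL8 and CX3CL1. CXCL8, the neutrophil attractant interleukin-8 (chromosome 4, 73740506 to 73743716), fell from 406 ± 12.3 CPM to 131 ± 9.77, 76.0 ± 1.84 and 108 ± 7.04 (n = 3 each). NID2 fell from 129 ± 5.98 CPM to 23.7 ± 0.712, 26.03 ± 1.14 and 39.8 ± 1.04, and RSAD2 from 79.0 ± 4.22 CPM to 12.7 ± 0.888, 14.6 ± 0.436 and 27.3 ± 2.46 (n = 3 each).

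In the mean of the 3 shRNAs against pLKO, the log2 fold change was 2.97 for TPM2 (SE 0.06, edgeR adjusted p = 8.81e-12), 2.59 for PRICKLE1 (SE 0.10, edgeR adjusted p = 1.15e-09) and 2.502 for ATP2B1 (SE 0.09, edgeR adjusted p = 4.49e-10). It was 2.42 for LRRN1 (SE 0.07, edgeR adjusted p = 1.61e-10) and 1.79 for INSIG1 (SE 0.06, edgeR adjusted p = 2.1e-10). Other genes with large shared rises were PDE10A, SERPINB8, STARD4, IDI1, LPAR1 and CHRDL1, from 1.83 for PDE10A to 1.48 for CHRDL1, with edgeR adjusted p of 8.68e-09 (IDI1) at most. The log2 fold change was -2.20 for RSAD2 (SE 0.06, edgeR adjusted p = 4.08e-11), -2.18 for CX3CL1 (SE 0.13, edgeR adjusted p = 4.86e-08), -2.15 for NID2 (SE 0.04, edgeR adjusted p = 7.06e-12) and -1.99 for CXCL8 (SE 0.05, edgeR adjusted p = 2.85e-11). OASL, DDX60, PCOLCE, IFI44, ISG15, TINAGL1 and VGF fell by -1.97 (OASL) to -1.59 (VGF), with edgeR adjusted p of 3.59e-06 (VGF) at most. PCOLCE, which encodes a procollagen processing enhancer, shares exonic sequence with PCOLCE-AS1, and the strand used in counting was not stated, so its value is uncertain.

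**Figure D3:**
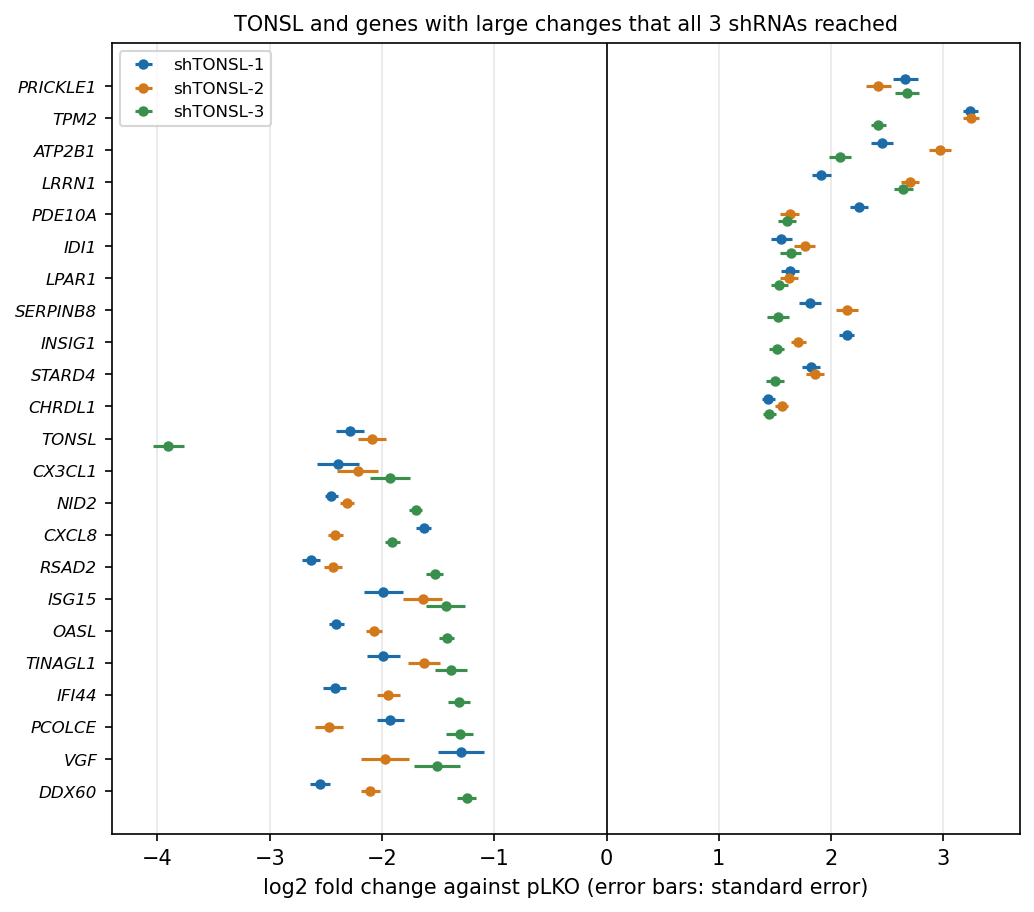
Log2 fold change against pLKO (x axis) of TONSL and of genes among those with the largest change that all 3 shRNAs reached (y axis); points are the 3 shRNA groups and error bars the standard error. TPM2 stands at 3.24, 3.24 and 2.42, RSAD2 at -2.63, -2.44 and -1.53, and TONSL at -2.29, -2.09 and -3.90 with shTONSL-1, shTONSL-2 and shTONSL-3.

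Of the genes in the table, 1535 were higher and 1297 lower than in pLKO with all 3 shRNAs, by edgeR's quasi-likelihood test in each. A further 108 passed in all 3 with unlike signs. At least a 2-fold change in all 3 was reached by 183 of the genes that rose and 119 of those that fell. Independent lists of these lengths would share 165 higher and 143 lower genes. Unchanged groups, simulated with controls drawn from the same pLKO means, shared 0 in 20 simulations. With no simulated change few genes can pass, so that 0 says little about the overlap. Of the genes called with shTONSL-1 and shTONSL-2, 4111 of 4224 had the same sign (97.3%). The shares were 3300 of 3478 (94.9%) for shTONSL-1 and shTONSL-3, and 3951 of 4106 (96.2%) for shTONSL-2 and shTONSL-3. No simulated share is given for these pairs, and shared controls can raise such shares. Across genes, Pearson's r of the fold changes was 0.828, 0.697 and 0.768 for these pairs (Spearman's rho 0.755, 0.592 and 0.681), against 0.503, 0.505 and 0.502 in the simulations. The covariances were 0.263, 0.187 and 0.226, against 0.0111, 0.0110 and 0.0110. With no simulated change and groups of equal size, a simulated r near 0.5 follows from the shared controls by design. It is therefore no baseline for the observed r. The 3 pLKO libraries were too few to divide between the comparisons. Noise of shared control libraries gave covariances that reached 0.0119 in the simulations. That argues against such noise as the main source of the observed covariances. The simulations held no difference of the pLKO population as a whole, which would move all 3 comparisons alike. Without shTONSL-3 replicate 2, the genes changed by all 3 shRNAs numbered 4383 in place of 2832.

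Genes of cholesterol synthesis rose together in the mean of the 3 shRNAs against pLKO. Of 23 tested members 21 rose, 0 fell and 2 did not pass, with 21 and 0 when adjusted over the list alone, and the median log2 fold change was 0.82 (camera adjusted p = 1.56e-11 and adjusted p = 0.0073 with an estimated correlation). The members with the smallest p were INSIG1 (1.79, SE 0.06), HMGCS1 (1.73, SE 0.06), MSMO1 (1.51, SE 0.06) and STARD4 (1.73, SE 0.07). HMGCS1 and MSMO1 are enzymes of the pathway, and STARD4 carries cholesterol between membranes. Fatty acid synthesis genes rose as well, with 9 of 12 members up, 1 down and 2 not passing, and 9 and 1 when adjusted over the list alone (median 0.26; camera adjusted p = 0.0151 and adjusted p = 0.211 with an estimated correlation). The desaturases SCD (1.17, SE 0.05), FADS2 (1.23, SE 0.10) and FADS1 (0.69, SE 0.08) rose, and malic enzyme ME1, which lies in a 10 Mb window whose genes shifted together, fell (-0.33, SE 0.06). The fatty acid list passed with shTONSL-1 and with shTONSL-2, but not with shTONSL-3 alone (camera adjusted p = 0.113). With shTONSL-3 it passed in 4 of 22 alternatives that kept camera's preset correlation. Among these were the GC correction (camera adjusted p = 0.0216) and leaving out shTONSL-3 replicate 2 (camera adjusted p = 0.0284, median 0.23).

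Interferon-response genes fell. Of 36 tested members 24 fell, 4 rose and 8 did not pass, with 24 down and 5 up when adjusted over the list alone, and the median was -0.79 (camera adjusted p = 1.04e-07 and adjusted p = 0.0724 with an estimated correlation). OASL (-1.97, SE 0.05), RSAD2 (-2.20, SE 0.06), DDX60 (-1.97, SE 0.06) and IFI44 (-1.89, SE 0.07) led the list. Inflammatory cytokines and NF-kB genes were also lower, with 16 of 26 down, 3 up and 7 not passing, and 16 and 3 when adjusted over the list alone (median -0.31; camera adjusted p = 0.00043 and adjusted p = 0.211 with an estimated correlation). CXCL8 (-1.99, SE 0.05), IL1B (-0.78, SE 0.04), IL6 (-1.04, SE 0.06) and CCL20 (-1.35, SE 0.07) had the smallest p. Taken alone, only shTONSL-3 moved this list past the threshold (camera adjusted p = 1.3e-09, against 0.0713 with shTONSL-1 and 0.317 with shTONSL-2). With shTONSL-1 this list passed in 3 of 22 alternatives with the preset correlation, among them without shTONSL-3 replicate 2 (camera adjusted p = 0.0387). Mesenchymal and EMT markers fell, with 20 of 30 down, 6 up and 4 not passing, and 21 and 6 when adjusted over the list alone (median -0.36; camera adjusted p = 0.0013 and adjusted p = 0.0807 with an estimated correlation). Examples were the matrix protein SPARC (-1.16, SE 0.04), the BMP antagonist GREM1 (-2.03, SE 0.08) and TGFB1 (-0.93, SE 0.06). The mesenchymal list passed with shTONSL-1 and with shTONSL-2, but not with shTONSL-3 alone (camera adjusted p = 0.0885). With shTONSL-3 it passed in 3 of 22 alternatives with the preset correlation. It passed without shTONSL-3 replicate 2 (camera adjusted p = 0.0465), but not after GC correction (camera adjusted p = 0.111).

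Replication-dependent histones rose, with 9 of 22 members up, 0 down and 13 not passing, and 9 and 0 when adjusted over the list alone (median 0.49; camera adjusted p = 0.0139 and adjusted p = 0.616 with an estimated correlation). The 4 with the smallest p were HIST1H2BK (1.29, SE 0.07), HIST1H2BD (0.98, SE 0.12), HIST1H1C (0.73, SE 0.11) and HIST1H2AC (0.31, SE 0.05), genes of families with near-identical copies whose reads the counting could divide. Mitosis and G2/M genes rose, with 16 of 40 up, 2 down and 22 not passing, and 16 and 2 when adjusted over the list alone (median 0.12; camera adjusted p = 0.0394 and adjusted p = 0.843 with an estimated correlation). KIF4A, BUB1, NUF2 and NDC80, which act on chromosomes and kinetochores, rose by 0.33 (NDC80) to 0.42 (NUF2). Hypoxia and glycolysis genes fell, with 14 of 33 down, 4 up and 15 not passing, and 14 and 4 when adjusted over the list alone (median -0.07; camera adjusted p = 0.0434 and adjusted p = 0.616 with an estimated correlation). The glucose transporter SLC2A3 (-1.94, SE 0.14) and ANGPTL4 (-1.74, SE 0.14) fell most among the 4 with the smallest p, with ENO2 at -0.63 (SE 0.06) and PFKFB3 at -0.39 (SE 0.04). The histone call ended without pLKO replicate 3 (camera adjusted p = 0.0599, and 0.00147 to 0.0599 over its 22 alternatives that kept camera's preset correlation), which was the 1 alternative of these to end it. The mitosis call passed in 17 of 22, and ended after GC correction (camera adjusted p = 0.175, range 0.0106 to 0.175), with DESeq2 statistics (0.133) and without pLKO replicate 1, 2 or 3 (0.0535, 0.0635 and 0.0599). The hypoxia call passed in 16 of 22, and ended after GC correction (camera adjusted p = 0.0718), without the genes of the shifted 10 Mb windows described last (0.104, range 0.0163 to 0.104), with the knockdown libraries as a single group (0.0766), and without pLKO replicate 2 (0.0564), pLKO replicate 3 (0.0883) or shTONSL-2 replicate 3 (0.0531). Taken alone, only shTONSL-3 moved the hypoxia list past the threshold (camera adjusted p = 8.54e-06, against 0.965 with shTONSL-1 and 0.317 with shTONSL-2). The same held for the mitosis list (camera adjusted p = 0.000545, against 0.965 and 0.0968). With shTONSL-2 the mitosis list passed in 2 of 22 alternatives, at the lowest without the genes of shifted windows (camera adjusted p = 0.0309). Histones did not pass with shTONSL-3 alone (camera adjusted p = 0.131).

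**Figure D4:**
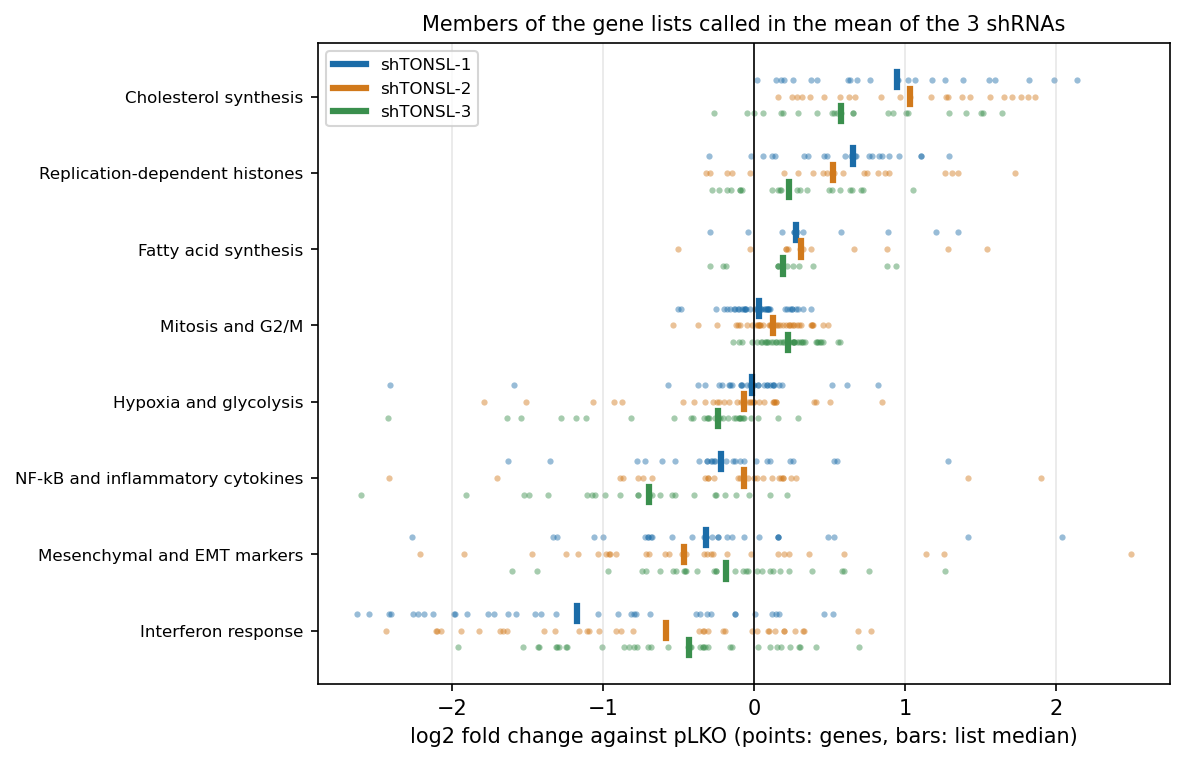
Log2 fold change against pLKO (x axis) of the tested members of the 8 gene lists that passed in the mean of the 3 shRNAs (y axis); points are genes, in a colour per shRNA, and vertical bars the list median. The medians for cholesterol synthesis are 0.95, 1.03 and 0.58 with shTONSL-1, shTONSL-2 and shTONSL-3, and those for the interferon response -1.17, -0.58 and -0.43; with an estimated correlation the interferon call held only with shTONSL-1.

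The known partners of TONSL and the fork histone-handling genes did not move as a list (median 0.03, mean -0.01; camera adjusted p = 0.916), with 2 of 20 up, 4 down and 14 not passing, and 2 and 4 when adjusted over the list alone. MMS22L, the direct binding partner of TONSL, fell (log2 fold change -0.46, SE 0.05; edgeR adjusted p = 1.93e-05), as did the chromatin assembly factor subunits CHAF1B (-0.21; edgeR adjusted p = 0.00447) and CHAF1A (-0.17; edgeR adjusted p = 0.00702), and WDHD1 (-0.17; edgeR adjusted p = 0.029). The histone H4K20 methyltransferase KMT5A rose (0.20; edgeR adjusted p = 0.000861), and so did the histone chaperone HIRA (0.16; edgeR adjusted p = 0.00553). With shTONSL-3 alone WDHD1 stood at 0.04 (edgeR adjusted p = 0.698), and at -0.14 after GC correction (edgeR adjusted p = 0.00635). CHAF1A stood at -0.17 with shTONSL-3 (edgeR adjusted p = 0.0244), and at 0.066 after GC correction (edgeR adjusted p = 0.428). Homologous recombination did not pass (camera adjusted p = 0.736; 7 of 32 up, 5 down, 20 not passing, and 7 and 5 when adjusted over the list alone). Nor did the Fanconi anaemia pathway (camera adjusted p = 0.227; 1 up, 4 down of 16, and 1 and 3 when adjusted over the list alone), nor replication licensing and elongation (camera adjusted p = 0.627; 11 up and 12 down of 39, the same numbers when adjusted over the list alone). Within these, RMI2 (0.95, SE 0.08) and BARD1 (0.56, SE 0.07) rose, while FANCB (-0.52, SE 0.07), ORC6 (-0.49, SE 0.05) and MCM6 (-0.32, SE 0.04) fell. RMI2 and FANCB lie in 10 Mb windows whose genes shifted together.

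Several other lists held strong changes of single genes without passing as lists. The p53 targets (camera adjusted p = 0.916; 8 up, 9 down of 26) held TP53I3 at 1.20 (SE 0.12) and GDF15 at -0.95 (SE 0.11). The apoptosis regulators (camera adjusted p = 0.736; 6 up, 9 down of 26) held BCL2 at 1.22 (SE 0.07) and PMAIP1 at -1.29 (SE 0.07). Among fibroblast and stromal markers (camera adjusted p = 0.627; 4 up, 4 down of 10), the actin-binding gene TAGLN rose by 3.10 (SE 0.08) and CXCL12 by 3.87 (SE 0.43). The leukocyte markers (camera adjusted p = 0.334; 1 up, 4 down of 5) held ITGAX at -1.37 (SE 0.16), and the endothelial markers (camera adjusted p = 0.736; 1 up, 1 down of 7) EGFL7 at -1.09 (SE 0.14). Telomere and shelterin genes (camera adjusted p = 0.744; 4 up, 1 down of 19) held TERT at -1.33 (SE 0.18), and epithelial and luminal markers (camera adjusted p = 0.736; 7 up, 5 down of 18) CLDN4 at -2.02 (SE 0.16). The immediate early genes (camera adjusted p = 0.325; 5 up, 9 down of 21) held DUSP6 at 1.69 (SE 0.18) and NR4A1 at -1.10 (SE 0.13). When adjusted over the list alone these counts were 8 and 9, 6 and 9, 5 and 4, 1 and 4, 0 and 1, 4 and 1, 7 and 5, and 5 and 11.

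The remaining lists did not pass either. ATF4 and unfolded protein response genes had 12 up and 5 down of 29 (camera adjusted p = 0.0959), MHC class I presentation 1 up and 6 down of 11 (camera adjusted p = 0.0684), and NRF2 targets 3 up and 11 down of 20 (camera adjusted p = 0.103). Collagen and matrix proteins had 9 up and 16 down of 28 (camera adjusted p = 0.157), YAP and TEAD targets 5 up and 8 down of 20 (camera adjusted p = 0.219), and the 8q24.3 genes next to TONSL 2 up and 11 down of 36 (camera adjusted p = 0.107). MYC targets and ribosome biogenesis had 9 up and 4 down of 39 (camera adjusted p = 0.79), cytoplasmic ribosomal proteins 6 up and 3 down of 46 (camera adjusted p = 0.944), and nuclear genes of oxidative phosphorylation 10 up and 5 down of 50 (camera adjusted p = 0.627). Heat shock and chaperone genes had 8 up and 2 down of 16 (camera adjusted p = 0.344), lysosome and autophagy genes 8 up and 7 down of 27 (camera adjusted p = 0.949), and the RNA interference machinery 5 up and 0 down of 13 (camera adjusted p = 0.316). When adjusted over the list alone these were 12 and 5, 1 and 6, 3 and 11, 10 and 16, 5 and 10, 1 and 9, 8 and 4, 2 and 0, 8 and 4, 8 and 2, 8 and 7, and 5 and 0. The median, the mean and the test differed in sign for the TONSL partners, homologous recombination, epithelial markers, cytoplasmic ribosomal proteins, telomere genes, lysosome genes and fibroblast markers. In the mean contrast 6803 genes passed edgeR's test, 3408 up and 3395 down, of which 372 and 286 changed at least 2-fold, and with library size alone 3238 rose and 3602 fell. With the 3 shRNA groups pooled against pLKO in a fit of their own, 4165 passed.

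With shTONSL-1, the interferon-response genes made up much of the strongest falls against pLKO. RSAD2 (-2.63, SE 0.08), DDX60 (-2.55, SE 0.09), IFI44 (-2.42, SE 0.10) and OASL (-2.41, SE 0.07) were among the genes that fell most, beside NID2 and CX3CL1. Sonic hedgehog, SHH, rose from 5.88 ± 0.185 to 29.2 ± 0.903 CPM (SD, n = 3), a log2 fold change of 2.31 (SE 0.07, edgeR adjusted p = 1.91e-10), and FAM83A rose by 2.25 (SE 0.14, edgeR adjusted p = 7.93e-08). Of 36 interferon-response genes 26 fell and 2 rose, with 27 and 2 when adjusted over the list alone (median -1.17; camera adjusted p = 3.35e-12 and adjusted p = 0.0172 with an estimated correlation). Cholesterol synthesis rose, with 20 of 23 up and 0 down, and 21 and 0 when adjusted over the list alone (median 0.95; camera adjusted p = 3.35e-12 and adjusted p = 0.00657 with an estimated correlation). YAP and TEAD targets were lower, with 8 of 20 down and 1 up, the same when adjusted over the list alone (camera adjusted p = 0.0115 and adjusted p = 0.16 with an estimated correlation), among them CYR61 (-0.96, SE 0.05) and the receptor kinase AXL (-0.68, SE 0.07). Collagen and matrix genes were lower, with 16 of 28 down and 7 up, and 17 and 7 when adjusted over the list alone (camera adjusted p = 0.0162 and adjusted p = 0.734 with an estimated correlation), although biglycan, BGN, rose by 1.61 (SE 0.10).

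Other lists that passed with shTONSL-1 were mesenchymal markers, down (camera adjusted p = 0.00116 and adjusted p = 0.0705 with an estimated correlation), histones, up (camera adjusted p = 0.00786 and adjusted p = 0.625 with an estimated correlation), and fatty acid synthesis, up (camera adjusted p = 0.0115 and adjusted p = 0.16 with an estimated correlation). MHC class I presentation fell, with 6 of 11 down and 0 up, the same when adjusted over the list alone (camera adjusted p = 0.0361 and adjusted p = 0.16 with an estimated correlation), among them B2M (-0.67, SE 0.08). ATF4 and unfolded protein response genes rose, with 15 of 29 up and 5 down, and 18 and 8 when adjusted over the list alone (camera adjusted p = 0.0497 and adjusted p = 0.16 with an estimated correlation), among them PSAT1 of serine synthesis (1.17, SE 0.05) and ATF4 (0.65, SE 0.05). The MHC call ended after GC correction (camera adjusted p = 0.0758, range 0.0247 to 0.0758 over 22 alternatives) and without pLKO replicate 1 (camera adjusted p = 0.0504). The ATF4 call ended with library size alone (camera adjusted p = 0.0572) and without pLKO replicate 1 (0.0719, range 0.00951 to 0.0719 over 22 alternatives). It also ended without shTONSL-1 replicate 1 (camera adjusted p = 0.0556), or shTONSL-2 replicate 1, 2 or 3 (0.0508, 0.0545 and 0.054). In all, 2862 genes rose and 2806 fell by edgeR's test, 462 and 324 of them at least 2-fold. The 5668 became 8549 without shTONSL-3 replicate 2, and 8657 with only shTONSL-1 and pLKO in the fit.

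With shTONSL-2, the rises of TPM2 (3.24, SE 0.07), ATP2B1 (2.97, SE 0.10) and LRRN1 (2.70, SE 0.08) were among the largest, beside those of PRICKLE1 and the insulin-like growth factor binding protein IGFBP5 (2.40, SE 0.13; edgeR adjusted p = 1.36e-08). PCOLCE, RSAD2, CXCL8, NID2 and CX3CL1 were among the genes that fell most, with the cyclooxygenase PTGS1 (-2.11, SE 0.08; edgeR adjusted p = 1.46e-09). Cholesterol synthesis rose, with 21 of 23 up and 0 down, the same when adjusted over the list alone (median 1.03; camera adjusted p = 6.23e-12 and adjusted p = 0.00651 with an estimated correlation). Interferon-response genes fell, with 20 of 36 down and 5 up, the same when adjusted over the list alone (median -0.58; camera adjusted p = 9.77e-05 and adjusted p = 0.171 with an estimated correlation). Mesenchymal and EMT markers fell, with 20 of 30 down and 6 up, and 21 and 8 when adjusted over the list alone (camera adjusted p = 0.00138 and adjusted p = 0.112 with an estimated correlation). SPARC fell by -1.92 (SE 0.05) and TGFBI by -1.17 (SE 0.05), while the collagen crosslinking enzyme LOX rose by 1.26 (SE 0.08). Fatty acid synthesis rose, with 9 of 12 up and 1 down, the same when adjusted over the list alone (camera adjusted p = 0.0198 and adjusted p = 0.25 with an estimated correlation). Histones rose, with 8 of 22 up and 0 down, and 7 and 0 when adjusted over the list alone (camera adjusted p = 0.0198 and adjusted p = 0.725 with an estimated correlation), led by HIST1H2BK (1.72, SE 0.08). The histone call ended without pLKO replicate 3 (camera adjusted p = 0.0603), without shTONSL-3 replicate 2 (camera adjusted p = 0.0533) and with only shTONSL-2 and pLKO in the fit (camera adjusted p = 0.0531), with a range of 0.00269 to 0.0603 over 22 alternatives. By edgeR's test 3319 genes rose and 3190 fell, 508 and 457 of them at least 2-fold.

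With shTONSL-3, which left the least TONSL mRNA, inflammatory cytokine genes fell most clearly. Of the 26 NF-kB and cytokine genes 22 fell and 0 rose, with 22 and 1 when adjusted over the list alone (median -0.70; camera adjusted p = 1.3e-09 and adjusted p = 0.0563 with an estimated correlation). CCL20 fell by -2.60 (SE 0.11), CXCL8 by -1.91 (SE 0.07), IL1B by -1.49 (SE 0.05) and IL6 by -0.99 (SE 0.07). Hypoxia and glycolysis genes fell, with 20 of 33 down and 1 up, the same when adjusted over the list alone (median -0.24; camera adjusted p = 8.54e-06 and adjusted p = 0.24 with an estimated correlation). Among them were the glycolytic genes ENO2 (-1.18, SE 0.08) and PFKFB3 (-0.82, SE 0.05) and the transporter SLC2A3 (-2.43, SE 0.20). Interferon-response genes fell, with 23 of 36 down and 6 up, and 24 and 6 when adjusted over the list alone (median -0.43; camera adjusted p = 8.54e-06 and adjusted p = 0.0894 with an estimated correlation). NRF2 targets fell, with 12 of 20 down and 1 up, and 13 and 1 when adjusted over the list alone (camera adjusted p = 0.00587 and adjusted p = 0.0789 with an estimated correlation), led by the aldo-keto reductase AKR1C1 (-1.34, SE 0.08). Cholesterol synthesis rose, with 15 of 23 up and 0 down, and 18 and 0 when adjusted over the list alone (median 0.58; camera adjusted p = 2.7e-08 and adjusted p = 0.0243 with an estimated correlation). Mitosis and G2/M genes rose, with 20 of 40 up and 0 down, and 23 and 0 when adjusted over the list alone (median 0.23; camera adjusted p = 0.000545 and adjusted p = 0.531 with an estimated correlation), among them KIF4A (0.42, SE 0.07), CCNA2 (0.41, SE 0.07) and KIF23 (0.57, SE 0.10).

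The 8q24.3 genes next to TONSL were lower with shTONSL-3, with 13 of 36 down and 1 up, and 12 and 1 when adjusted over the list alone (median -0.28; camera adjusted p = 0.00768 and adjusted p = 0.768 with an estimated correlation), among them DGAT1 (-0.66, SE 0.09) and KIFC2 (-0.92, SE 0.14). That call ended without shTONSL-3 replicate 2 (camera adjusted p = 0.125) and turned direction after GC correction (camera adjusted p = 0.387, range 0.000442 to 0.387 over 22 alternatives). Without that library the medians of the other called lists were -0.66 for NF-kB, -0.22 for hypoxia, -0.53 for interferon, -0.22 for NRF2, 0.66 for cholesterol and 0.15 for mitosis, and that of the 8q24.3 genes was -0.08. Among single genes, SUSD5 rose by 1.85 (SE 0.08, edgeR adjusted p = 1.07e-08), the Notch target HES4 fell by -1.67 (SE 0.22, edgeR adjusted p = 8.94e-05) and TMEM156 by -1.57 (SE 0.12, edgeR adjusted p = 1.19e-06). TMEM156 stood at 0.00 with shTONSL-1 (edgeR adjusted p = 0.998). By edgeR's test 3368 genes rose and 3097 fell, 285 and 391 of them at least 2-fold. With library size alone the balance turned, with 2941 up and 3507 down. With only shTONSL-3 and pLKO in the fit, 3804 passed in place of 6465.

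The shRNAs were then compared with each other, as the series used 3 against the same gene. Between shTONSL-2 and shTONSL-1, SHH showed a large difference, from 29.2 ± 0.903 CPM with shTONSL-1 to 4.31 ± 0.137 with shTONSL-2 (SD, n = 3; log2 difference -2.76, SE 0.07; edgeR adjusted p = 3.9e-10). CD163L1 (2.07, SE 0.13), the lectin-like LDL receptor OLR1 (1.80, SE 0.07), the matrix gene FBLN1 (1.56, SE 0.06) and SAA1 (1.47, SE 0.12) were higher with shTONSL-2, and STMN3 (-1.44, SE 0.15), FAM83A (-1.30, SE 0.13) and SHISA2 (-1.23, SE 0.10) lower. By edgeR's test 1578 genes were higher and 1514 lower, 233 of them at least 2-fold. The 3092 became 6403 without shTONSL-3 replicate 2, 5313 after GC correction, 6654 with only these groups in the fit, and 1979 without shTONSL-1 replicate 2 and likewise without replicate 3.

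Between shTONSL-3 and shTONSL-1, the growth factor BMP5 (1.68, SE 0.09), the guidance factor SEMA3A (1.67, SE 0.10), HECW2 (1.54, SE 0.07) and MATN2 (1.504, SE 0.08) were higher with shTONSL-3. The granulocyte colony-stimulating factor CSF3 (-2.34, SE 0.14), DDIT4 (-1.73, SE 0.13) and SHH (-1.64, SE 0.07) were lower. Between shTONSL-3 and shTONSL-2, SPARC (1.67, SE 0.05), BMP5 (1.63, SE 0.09), SHISA2 (1.48, SE 0.10) and CXCL14 (1.42, SE 0.09) were higher with shTONSL-3, and CSF3 (-2.95, SE 0.14), PI3 (-2.08, SE 0.10) and PTX3 (-1.81, SE 0.05) lower. CSF3 stood at 10.5 ± 0.322 CPM in pLKO, 25.6 ± 3.53 with shTONSL-1, 38.99 ± 2.34 with shTONSL-2 and 5.03 ± 1.06 with shTONSL-3 (SD, n = 3 each), so that it moved in opposite directions against pLKO (1.29, 1.90 and -1.06; edgeR adjusted p = 7.2e-06, 1.84e-07 and 9.06e-05). SPARC stood at 703 ± 13.2 CPM in pLKO and at 284 ± 3.32, 186 ± 6.74 and 590 ± 20.3 with the 3 shRNAs (n = 3 each). By edgeR's test 2715 genes were higher and 2498 lower with shTONSL-3 than with shTONSL-1 (125 and 308 at least 2-fold), and 2445 higher and 2286 lower than with shTONSL-2 (117 and 191). With library size alone the balance turned in both, with 2276 higher and 2839 lower, and 2137 higher and 2610 lower. With only the compared groups in the fit these totals fell from 5213 to 2566 and from 4731 to 2020.

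Genes close to each other on a chromosome changed together, a comparison chosen after the data were seen. Most of the 17 genes in the window at the end of the long arm of chromosome 18 (70000001 to 80000000, hg38) were higher, with medians of 0.98, 0.99 and 0.68 with shTONSL-1, shTONSL-2 and shTONSL-3. In this window CNDP2 stood at 1.38, 1.61 and 1.09 and TIMM21 at 1.36, 1.45 and 1.25, while NFATC1 stood at -0.81, -0.75 and -0.57; these genes were chosen after their values were seen. The window on chromosome 4 from 180000001 to 190000000 (21 genes) had medians of 0.62, 0.79 and 0.49. On chromosome 5, the windows from 1 to 10000000 (23 genes) and from 10000001 to 20000000 (15 genes) had medians of -0.48, -0.62 and -0.23, and -0.58, -0.90 and -0.17. Of 255 windows of 10 Mb, each with at least 15 genes at a log2 CPM of 2 or more, 29 had a median in the mean contrast past the 0.271 reached by the most extreme window in 5% of 1000 shuffles of gene positions, 20 up and 9 down. These held 836 of the 10352 genes, and 655 of the 836 passed edgeR's test in the mean contrast. Of the genes named above, IDI1, CHRDL1, ME1, PFKFB3, AKR1C1, RMI2, FANCB and STMN3 lie in these windows, as does TERT, whose expression was too low for it to count towards a window's median.

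**Figure D5:**
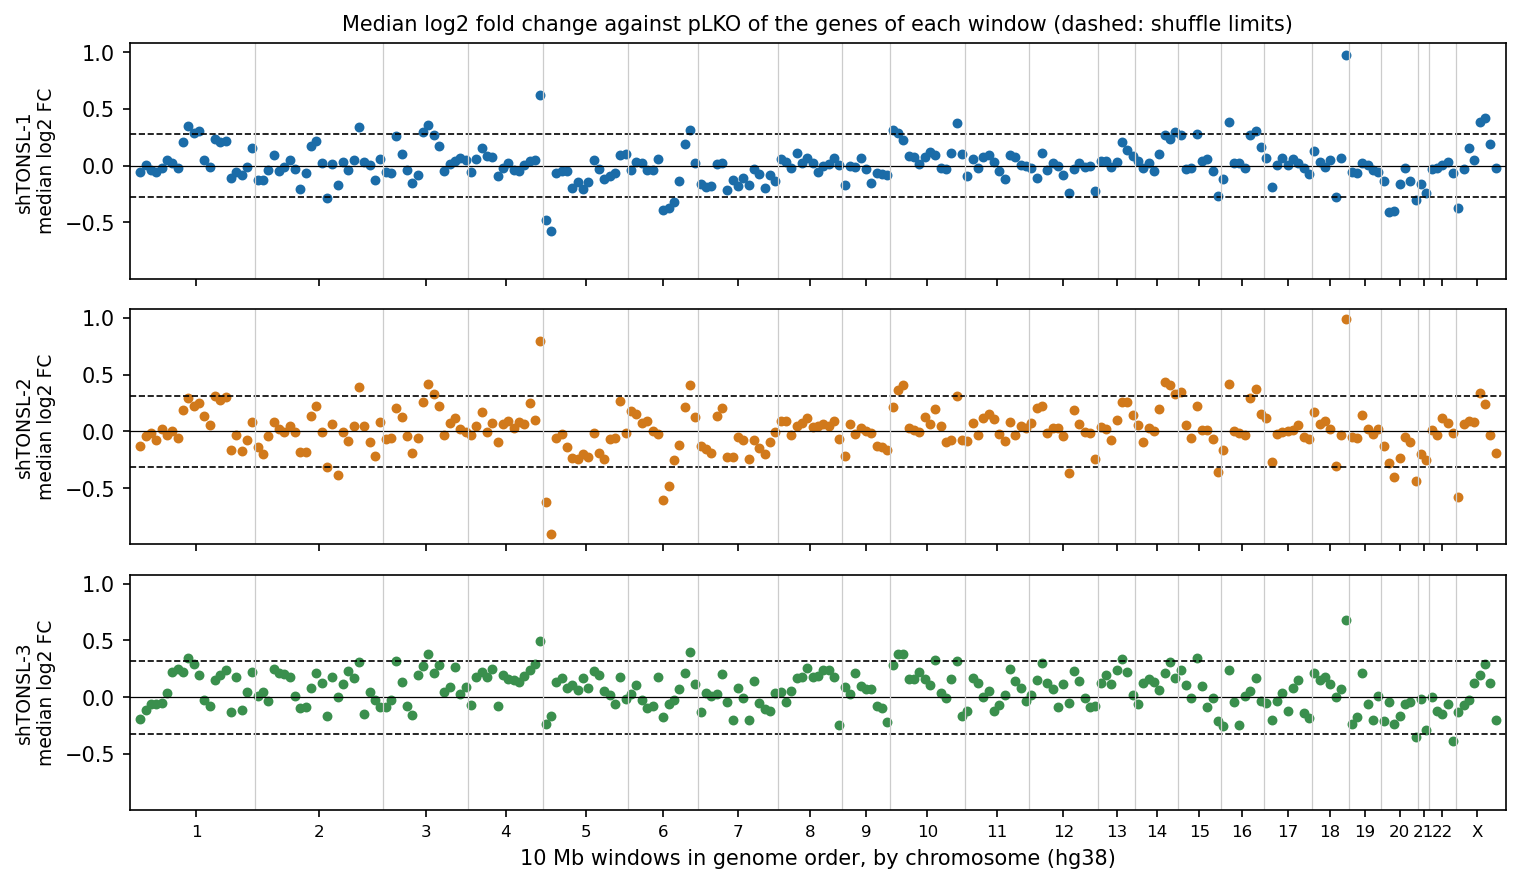
Median log2 fold change against pLKO (y axis) of the genes in each of 255 windows of 10 Mb in genome order (x axis, hg38), a panel per shRNA; points are windows and dashed lines the limits from 1000 shuffles of gene positions. Past the limits lie 27 windows with shTONSL-1, 28 with shTONSL-2 and 12 with shTONSL-3, the highest on chromosome 18 at 0.98, 0.99 and 0.68.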

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

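The weighing of the interferon response below used tests that follow the depth of TONSL loss and ask for a hairpin control, both chosen only after the result was seen. All results in this part were differences between shRNAs against the same gene that passed a test of the difference itself. None of the list differences passed with an estimated correlation, whose adjusted p follows each. shTONSL-3 held the library with the GC-dependent difference, and calls that it or another alternative ended are given with the range over 22 alternatives.

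TONSL itself differed by -1.616 between shTONSL-3 and shTONSL-1 (edgeR adjusted p = 2.94e-06) and by -1.811 between shTONSL-3 and shTONSL-2 (edgeR adjusted p = 1.29e-06). Between shTONSL-2 and shTONSL-1, interferon-response genes were higher with shTONSL-2 by a median log2 difference of 0.365, with 24 of 36 up, 0 down and 12 not passing, and 26 and 1 when adjusted over the list alone (camera adjusted p = 3.65e-09 and adjusted p = 0.0633 with an estimated correlation). The antiviral genes SAMD9L (1.09, SE 0.11), BST2 (1.83, SE 0.20) and IFIT2 (0.83, SE 0.11) had the smallest p. NRF2 targets were lower by -0.1855, with 9 of 20 down and 1 up, and 11 and 2 when adjusted over the list alone (camera adjusted p = 0.00395 and adjusted p = 0.0633 with an estimated correlation), among them AKR1C1 (-0.94, SE 0.08) and SRXN1 (-0.53, SE 0.05). Without the genes of shifted windows this missed the threshold (camera adjusted p = 0.0546, range 4.96e-05 to 0.0546). Mitosis and G2/M genes were higher by 0.1042, with 6 of 40 up and 0 down, the same when adjusted over the list alone (camera adjusted p = 0.0378 and adjusted p = 0.795 with an estimated correlation), and passed in 17 of 22 alternatives. It missed the threshold without shTONSL-1 replicate 3 (camera adjusted p = 0.118, range 0.00369 to 0.118), pLKO replicate 1 (0.051) or shTONSL-2 replicate 2 or 3 (0.0532 and 0.102), and with DESeq2 statistics (0.069).

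Between shTONSL-3 and shTONSL-1, NF-kB and cytokine genes were lower with shTONSL-3 by a median of -0.4083, with 17 of 26 down and 2 up, and 18 and 2 when adjusted over the list alone (camera adjusted p = 6.34e-07 and adjusted p = 0.0991 with an estimated correlation), led by IL1B (-1.50, SE 0.05), CCL20 (-1.83, SE 0.11) and CSF3 (-2.34, SE 0.14). Hypoxia and glycolysis genes were lower by -0.267, with 18 of 33 down and 1 up, and 21 and 1 when adjusted over the list alone (camera adjusted p = 1.62e-05 and adjusted p = 0.183 with an estimated correlation), among them NDRG1 (-1.05, SE 0.06). NRF2 targets were lower by -0.2132, with 11 of 20 down and 1 up, the same when adjusted over the list alone (camera adjusted p = 0.00115 and adjusted p = 0.056 with an estimated correlation), with AKR1C1 at -1.42 (SE 0.08) and HMOX1 at -1.08 (SE 0.12). Cholesterol synthesis was lower by -0.3065, with 10 of 23 down and 0 up, and 11 and 1 when adjusted over the list alone (camera adjusted p = 0.00176 and adjusted p = 0.0991 with an estimated correlation), and the median was -0.1541 without shTONSL-3 replicate 2. YAP and TEAD targets were higher by 0.2126, with 9 of 20 up and 1 down, the same when adjusted over the list alone (camera adjusted p = 0.003 and adjusted p = 0.0991 with an estimated correlation), among them CYR61 (0.61, SE 0.05) and CTGF (0.63, SE 0.06). Mitosis and G2/M genes were higher by 0.1947, with 18 of 40 up and 0 down, and 20 and 0 when adjusted over the list alone (camera adjusted p = 0.000917 and adjusted p = 0.55 with an estimated correlation), among them the checkpoint kinase TTK (0.68, SE 0.09), which lies in a shifted window, and the median was 0.1111 without shTONSL-3 replicate 2.

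Collagen and matrix genes were also higher with shTONSL-3 than with shTONSL-1, by 0.1425, with 13 of 28 up and 4 down, and 13 and 5 when adjusted over the list alone (camera adjusted p = 0.0126 and adjusted p = 0.564 with an estimated correlation), among them LAMA4 (1.69, SE 0.10) and FBLN1 (1.12, SE 0.06). Mesenchymal markers were higher by 0.1756, with 12 of 30 up and 4 down, the same when adjusted over the list alone (camera adjusted p = 0.0268 and adjusted p = 0.183 with an estimated correlation), led by SPARC (1.06, SE 0.05). Without shTONSL-3 replicate 2 the medians were 0.3003 for collagen and matrix genes and 0.09253 for mesenchymal markers. Without shTONSL-3 replicate 3 both missed the threshold (camera adjusted p = 0.0936, range 8.36e-06 to 0.0936, and 0.0501, range 0.00208 to 0.0501). Homologous recombination genes were higher by 0.2219, with 16 of 32 up and 2 down, and 17 and 2 when adjusted over the list alone (camera adjusted p = 0.0147 and adjusted p = 0.568 with an estimated correlation), among them GEN1 (0.48, SE 0.09). The 8q24.3 genes were lower by -0.1856, with 7 of 36 down and 2 up, and 6 and 2 when adjusted over the list alone (camera adjusted p = 0.0236 and adjusted p = 0.727 with an estimated correlation), among them NRBP2 (-0.59, SE 0.10). Both missed the threshold after GC correction (camera adjusted p = 0.114 and 0.56, the latter with the direction turned) and without shTONSL-3 replicate 2 (camera adjusted p = 0.124 and 0.74, medians 0.1096 and -0.02969), with ranges of 0.00314 to 0.124 and 0.00127 to 0.74. The 8q24.3 call also ended with DESeq2 statistics (camera adjusted p = 0.0863).

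Between shTONSL-3 and shTONSL-2, NF-kB and cytokine genes were again lower with shTONSL-3, by -0.5409, with 20 of 26 down and 1 up, and 21 and 2 when adjusted over the list alone (camera adjusted p = 1.23e-07 and adjusted p = 0.105 with an estimated correlation), among them CCL20 (-1.93, SE 0.11) and CXCL1 (-0.74, SE 0.06). Cholesterol synthesis was lower by -0.3945, with 16 of 23 down and 0 up, and 17 and 1 when adjusted over the list alone (camera adjusted p = 1.89e-05 and adjusted p = 0.0902 with an estimated correlation), among them FDPS (-0.46, SE 0.06). Hypoxia and glycolysis genes were lower by -0.205, with 17 of 33 down and 2 up, and 20 and 2 when adjusted over the list alone (camera adjusted p = 0.00123 and adjusted p = 0.33 with an estimated correlation). Collagen and matrix genes were higher by 0.2671, with 15 of 28 up and 4 down, the same when adjusted over the list alone (camera adjusted p = 0.00253 and adjusted p = 0.409 with an estimated correlation), with COL5A2 at 0.90 (SE 0.05) and COL8A1 at -0.99 (SE 0.07), and the median was 0.4345 without shTONSL-3 replicate 2. MYC targets and ribosome biogenesis genes were higher by 0.1561, with 19 of 39 up and 0 down, the same when adjusted over the list alone (camera adjusted p = 0.00518 and adjusted p = 0.137 with an estimated correlation), among them UTP20 (0.66, SE 0.08) and DDX21 (0.52, SE 0.07). Replication genes were higher by 0.0916, with 10 of 39 up and 1 down, and 7 and 1 when adjusted over the list alone (camera adjusted p = 0.0152 and adjusted p = 0.33 with an estimated correlation), led by ORC6 (0.74, SE 0.07) and MCM6 (0.39, SE 0.04).

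The remaining differences between shTONSL-3 and shTONSL-2 depended on single libraries. Interferon-response genes were higher with shTONSL-3 by 0.1558, with 16 of 36 up and 5 down, the same when adjusted over the list alone (camera adjusted p = 0.0207 and adjusted p = 0.33 with an estimated correlation), with RSAD2 at 0.91 (SE 0.08) and BST2 at -2.15 (SE 0.20). Homologous recombination genes were higher by 0.1805, with 11 of 32 up and 3 down, and 13 and 3 when adjusted over the list alone (camera adjusted p = 0.0267 and adjusted p = 0.573 with an estimated correlation), among them BLM (0.45, SE 0.09), which lies in a shifted window. Lysosome and autophagy genes were lower by -0.1861, with 12 of 27 down and 3 up, the same when adjusted over the list alone (camera adjusted p = 0.0267 and adjusted p = 0.33 with an estimated correlation), among them LAMP1 (-0.49, SE 0.05). Without shTONSL-3 replicate 2 these became camera adjusted p = 0.0552 (range 0.0125 to 0.0552), 0.132 (range 0.0111 to 0.132) and 0.109 (range 0.0148 to 0.109), with medians of 0.1704, 0.07353 and -0.1202. Homologous recombination and lysosome genes also missed the threshold after GC correction (camera adjusted p = 0.0928 and 0.0684), homologous recombination with DESeq2 statistics (camera adjusted p = 0.0576), and lysosome genes without the genes of shifted windows (camera adjusted p = 0.0568). Mesenchymal markers were higher by 0.09336, with 11 of 30 up and 4 down, and 14 and 4 when adjusted over the list alone (camera adjusted p = 0.0267 and adjusted p = 0.305 with an estimated correlation), and missed the threshold without shTONSL-3 replicate 1 (camera adjusted p = 0.0574, range 3.4e-05 to 0.0574).

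Interferon-response genes fell less with shTONSL-3, which left the least TONSL mRNA, than with shTONSL-1. The list was higher with shTONSL-3 than with shTONSL-1 by a median of 0.5511, with 25 of 36 up, 1 down and 10 not passing, and 26 and 1 when adjusted over the list alone (camera adjusted p = 5.59e-10 and adjusted p = 0.056 with an estimated correlation), among them DDX60 (1.31, SE 0.08) and IFIT3 (1.25, SE 0.09). For this list, the direction is opposite to a response that grows with the depth of TONSL mRNA loss alone. That restates the difference itself and is not a separate test. A pull of shTONSL-3 replicate 2 towards the control is argued against, since the median difference was 0.6694 without that library. A response to hairpin expression that differs between shRNAs cannot be told apart, since the labels name 0 groups with a hairpin against no human gene and do not say whether pLKO carries one.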

How the results depend on the processing

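The GC correction and the fits without the genes of shifted windows were chosen only after results were seen, and shTONSL-3 replicate 2 was singled out then. Of 24087 comparisons of 1010 named-gene results with 24 alternatives, 22668 kept their direction and side of the threshold, 1233 no longer passed (651 of them under the 2-fold threshold), 179 passed newly and 7 reversed. Of 5586 comparisons of 224 list results, 5347 kept both, 117 no longer passed (48 with an estimated correlation), 118 passed newly and 4 reversed. For the changes below the cause was not tested, except where a stricter threshold or fewer libraries give it by construction. Scaling moved the median log2 change of all genes by -0.0425 at the furthest (shTONSL-3 against pLKO, library size alone), and filterByExpr removed 0 genes, so the alternative without it says nothing. The pseudocount alternative was not run, since counts were given. Numbers up and down were near balance, and the balance turned in other alternatives too, among them 1590 and 1608 for shTONSL-2 against shTONSL-1 with library size alone, 3370 and 3418 in the mean contrast with DESeq2 size factors, and after GC correction 3640 and 4028 (shTONSL-1), 4068 and 4213 (shTONSL-2), 4021 and 4339 (mean) and 1937 and 1957 (all 3 shRNAs). They were 4203 and 4346 (shTONSL-1) and 3138 and 3265 (shTONSL-2 against shTONSL-1) without shTONSL-3 replicate 2, 971 and 1008 for the latter without shTONSL-1 replicate 2, and 1275 and 1291 for shTONSL-3 against shTONSL-1 with only those groups in the fit.

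The 7 gene reversals came after GC correction. With shTONSL-3 these were CHAF1A (0.065503, edgeR adjusted p = 0.428, from -0.17), FOXF2 (0.21115, edgeR adjusted p = 0.145, from -0.22), HSPB1 (0.0096175, edgeR adjusted p = 0.937, from -0.44), RBBP4 (-0.090801, edgeR adjusted p = 0.0406, from 0.06), CABIN1 (0.16377, edgeR adjusted p = 0.00426, from -0.11) and WDHD1 (-0.14376, edgeR adjusted p = 0.00635, from 0.04), and in the mean contrast RPL35 (0.11035, edgeR adjusted p = 0.447, from -0.15). The list reversals were the 8q24.3 genes after GC correction (camera adjusted p = 0.387 with shTONSL-3 and 0.56 for shTONSL-3 against shTONSL-1) and apoptosis regulators by fry (fry adjusted p = 0.039 with shTONSL-1 and 0.0168 with shTONSL-2).

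Contrasts below run in the order shTONSL-1, shTONSL-2, shTONSL-3 and their mean against pLKO, then shTONSL-2 against shTONSL-1, shTONSL-3 against shTONSL-1 and shTONSL-3 against shTONSL-2. With only the compared groups in the fit, genes numbered 8657 (shTONSL-1), 3804 (shTONSL-3), 4165 (mean), 6654, 2566 and 2020 (the pairs), and TONSL differed by 0.19472 between shTONSL-2 and shTONSL-1 (edgeR adjusted p = 0.00214, range 0.00214 to 0.471, the highest without shTONSL-1 replicate 2). At a 2-fold change genes numbered 786, 965, 676, 658, 233, 433 and 308, and 302 for all 3 shRNAs. At an adjusted p under 0.01 they numbered 4126 (shTONSL-3), 1664, 2879 and 2616 (the pairs) and 1794 (all 3), and lists 4 (shTONSL-1), 3 (shTONSL-2), 4 (mean), 7 and 5 (shTONSL-3 against shTONSL-1 and shTONSL-2). Lists numbered 2, 1, 1, 1, 0, 0 and 0 by camera with an estimated correlation, 14, 23, 18, 18, 13, 18 and 19 by fry, and 11 with shTONSL-3 by DESeq2. After GC correction 5313 genes passed for shTONSL-2 against shTONSL-1, and TONSL differed by 0.26509 (edgeR adjusted p = 0.00347). With genes of a log2 CPM of at least 3, the correlation of shTONSL-2 and shTONSL-3 was 0.69993.

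Leaving out each library in turn gave 4493 to 8549, 5540 to 9100, 5142 to 7488, 5402 to 9025, 1979 to 6403, 3487 to 6352 and 3269 to 5985 genes, and 2223 to 4383 for all 3 shRNAs. Without shTONSL-3 replicate 2, these were 8549 (shTONSL-1), 6403 (shTONSL-2 against shTONSL-1) and 4383 (all 3), and 1979 stood without shTONSL-1 replicate 2 or replicate 3. Lists numbered 7 to 10, 4 to 5, 7 to 9, 5 to 9 (5 without pLKO replicate 3), 2 to 3, 9 to 13 and 7 to 13, and TONSL differed by 0.18224 to 0.20495 between shTONSL-2 and shTONSL-1 (0.18923 without shTONSL-3 replicate 2, edgeR adjusted p = 0.00715). With the replicate number as a block, 5358, 6245, 6138, 6509, 2696, 4810 and 4352 genes passed. The numbers did not pair the libraries: of 18 pairs with like numbers 1 had a correlation over 0.1 (-0.253 to 0.115), and 2 of 12 libraries correlated best with their own number.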

Other observations

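The shuffles of gene positions and the depth test of shTONSL-3 replicate 2 were tests chosen only after the results were seen, and the copy-number test was set after the window pattern was seen. BMP5, a growth factor of the bone morphogenetic family, fell by -2.08 with shTONSL-1, -2.02 with shTONSL-2 and -0.40 with shTONSL-3. The elastase inhibitor PI3 stood at 1.54, 2.01 and -0.06 with shTONSL-1, shTONSL-2 and shTONSL-3, and the pentraxin PTX3 at 0.31, 1.60 and -0.21.

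In shTONSL-3 replicate 2, the difference from its groupmates followed transcript GC content (rho = -0.7824), with 57.82% of its variance explained by GC content, against 5.243% or less in the libraries outside its group. By the same measure shTONSL-3 replicates 1 and 3 stood at 35.77% and 41.91%, with rho of the opposite sign (0.672 and 0.6802). Each of them was compared with groupmates that include replicate 2. GC-dependent recovery in library preparation or sequencing is a candidate explanation. Sequencing depth is excluded, since its 61.3 M counts lay within the range of the other libraries. A stronger response to TONSL loss in that sample cannot be told apart by the correlation of its difference with the mean effect of shTONSL-1 and shTONSL-2, which was weak (r = 0.108).

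Genes in some 10 Mb windows shifted together, and 0 of 1000 shuffles of gene positions gave a window median as extreme, which excludes chance clustering. GC content and expression level are excluded for the most shifted window, on chromosome 18, since 328 genes elsewhere matched on both had a median of -0.007794. A copy-number difference between the pLKO and shTONSL cell populations may account for the shifts: 181 of 237 low-expressed genes not used to choose the windows (76.37%, 95% interval 70.44 to 81.63) went the way of their window, although the interval spans the bound of 75% set for this test and is too narrow, as it takes neighbouring genes as independent. This was the test tried after another, on the 17 genes of the most shifted window (94.12% the same way, 87.5% in its least uniform part), had been set aside because that window had been chosen for its shift, and both the pattern and that outcome had been seen. Regional regulation would give the same pattern, and no DNA was measured.

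Other divisions of the libraries into groups of the same sizes were tried for each count of calls. For the mean of the 3 shRNAs, 1 of 100 divisions gave as many genes, the real one (4165 against 938 in the next, which set the shTONSL-2 libraries against others), so chance spread between libraries is excluded. For genes changed by all 3 shRNAs it was 1 of 100 (2832 against 110), so that spread is excluded there too. These divisions do not exclude a chance difference of the pLKO population as a whole, since replicates may be technical. For the lists called in the mean of the 3 shRNAs it was 38 of 100 (7 against 12), so chance is not excluded for that number. With 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real values and the highest others for genes were 8653 and 0 (shTONSL-1), 8817 and 0 (shTONSL-2), 3802 and 0 (shTONSL-3), 6650 and 0 (shTONSL-2 against shTONSL-1), 2566 and 0 (shTONSL-3 against shTONSL-1) and 2020 and 0 (shTONSL-3 against shTONSL-2), each reached by 1 split. For lists they were, in that order, 9 and 7 (1 split as large), 5 and 10 (5 splits), 7 and 9 (3 splits), 3 and 8 (8 splits), 11 and 9 (1 split), and 11 and 8 (1 split).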
